A study of Mus musculus with 9 samples.

How the data were processed

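Liver RNA of 9 female mice was measured on Affymetrix whole-transcript arrays, 1 array per mouse. The labels give 3 groups of 3 individual mice each. The control group carried floxed alleles of both corepressor genes with no deletion, the SMRT KO group lacked SMRT in the liver, and the double KO group lacked both SMRT and NCoR in the liver. The mice were 7 to 9 weeks old, on standard chow, euthyroid and of a mixed 129SV/B6 background, and 200 ng of total RNA per liver was amplified and labelled with biotin. Each group was taken from the sample titles and each array column was matched to its sample by name, with 0 columns left over.

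The deposited table holds log2 expression values, 1 per probe set and array, which the authors made with RMA per the submitters' processing notes. RMA subtracts background, quantile-normalizes the arrays against each other and summarises the probes of a probe set. Its version is not given in the sources used here. Because all arrays were normalized together, a change shared by most genes would not show in these values. The log2 scale of the values was checked on the table, where array medians lay between 5.96 and 6.02 over all probe sets. Arrays carry no read depth, and the number of arrays limits the precision of every estimate.

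The table holds 41345 probe sets. The platform annotation used here gave exactly 1 gene symbol to 23521 of them and several symbols to 1814, and it did not list 16010, of which 190 were control probe sets. Symbols were compared through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, in which 23328 single-symbol probe sets were found and 0 symbols had to be renamed. That table was used for names and for which genes neighbour each other, and no coordinates are given. Probe sets with exactly 1 symbol were kept, with the probe set of the highest mean over the 9 arrays where a gene had several, as 1082 genes did. This left 22180 genes, with no filter on level. The genotypes in the labels were not checked here, and 1 planned result is not reported.

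Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided) in a single model over all 9 arrays with no block, which gave 6 residual and 3.36 prior degrees of freedom. The 3 contrasts were SMRT KO against control, double KO against control and double KO against SMRT KO. P-values were adjusted by the Benjamini-Hochberg method over genes within each contrast, and a gene was called below an adjusted p of 0.05. All adjusted p-values of single genes come from limma. With 3 mice against 3, an exact permutation test of a single gene cannot go below p = 0.1, so none was used. Errors are standard errors of the log2 fold change from the model, or standard deviations over the 3 mice of a group. The steps were tested on simulated data with 200 genes changed among 22180. At 1.5-fold, 63% of the changed genes were recovered for SMRT KO against control, 70.5% for double KO against control and 71.5% for double KO against SMRT KO. At 2-fold these shares were 95%, 93.5% and 96%. With 200 changed genes the adjusted threshold is easier to pass than where few genes change. The shares therefore do not give the chance that a real change of that size is called. In SMRT KO against control, Cyp26a1 was 5.53-fold higher and did not pass. The 3 contrasts have the same standard errors, so their shares differ through the simulated draws.

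The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 28 lists covered the corepressor complex, thyroid hormone-induced liver genes, fatty acid and triglyceride synthesis, lipid droplets and storage, fatty acid oxidation and ketogenesis, cholesterol synthesis and uptake, LXR targets, bile acids, glucose production and use, the circadian clock, xenobiotic metabolism, female-biased and male-biased liver genes, NRF2 targets, ER stress, the acute phase, the interferon response and the cell cycle. The others held markers of hepatocytes, macrophages, stellate cells, endothelium, cholangiocytes, lymphocytes, neutrophils, erythroid cells, pancreatic acini and adipocytes. Lists with at least 5 measured members, 27 of the 28, were tested with limma's camera at a preset correlation of 0.01, adjusted over all 81 pairs of list and contrast. Camera was repeated with the correlation estimated from the data. The fry test, which asks whether a list's genes move on balance in a single direction and does not compare them with other genes, was run beside it. Of the 81 pairs, 30 passed with the preset correlation, 0 with the estimated correlation and 15 by fry. For all 30 the estimated correlation gave the highest adjusted p of the 14 alternatives run on the lists, so the p given with it is the upper end of that list's range. Counts of called members are given over all genes and adjusted over the list alone.

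Named genes followed a fixed rule for each contrast. It took the thyroid hormone-responsive genes Thrsp, Dio1, Me1 and Fasn whatever their result, and the 5 highest and 5 lowest fold changes among called genes whose groups did not overlap. It also took up to 4 called members with the largest changes from each list that passed camera or had at least 2 called members. Where fewer than 10 genes passed, it took the 5 higher and 5 lower genes with the smallest p. Unnamed and predicted genes were passed over in the parts that rank by fold change or p. Genes named outside the rule are said to have been chosen after their values were seen.

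Alternatives to the main settings were a filter that left out the 40% of genes with the lowest mean, a second quantile normalization, subtraction of array medians, eBayes with trend and robust estimation, a fit of only the 2 groups compared, the replicate number as a block, array weights, the mean of all probe sets of a gene, a 1.5-fold minimum, an adjusted p of 0.10, and leaving out each mouse in turn. Cyclic loess normalization and a fit without the 400 genes nearest Ncor1 were added after the data were seen. Unchanged groups against the same controls were simulated 100 times, because both knockouts were set against the same 3 control arrays, and 100 more times with the changes of the called genes added to the double KO group alone.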

Results

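NCoR1 and SMRT are nuclear receptor corepressors, proteins that bind thyroid hormone receptors and related receptors and hold their target genes at a low level. The series asks how each of them acts on liver gene expression, in particular on thyroid hormone signalling. Livers were profiled from 3 control mice with floxed alleles and no deletion, 3 SMRT KO mice lacking SMRT in the liver, and 3 double KO mice lacking both corepressors there. All 9 mice were euthyroid females, with normal thyroid hormone status. No group lacking NCoR1 alone is among the samples. Loss of NCoR1 can be seen here only where SMRT is already absent, as the difference between double KO and SMRT KO mice. That difference would also hold any difference in genetic background between these groups. The same limit applies to each knockout set against control. The labels do not give the Ncor1 allele of the SMRT KO mice. Over all deposited probe sets, the correlation between arrays was 0.987 to 0.992 within groups and 0.983 to 0.989 between groups. The first principal component, with 28.6% of the variance, placed the 3 double KO livers at 17.1 to 20.8 and the other 6 livers at -12.2 to -6.39. The second, with 16.0%, set control replicate 1 at -20.6 and SMRT KO replicate 3 at 15.5, at opposite ends. The 3 SMRT KO livers lay at 4.82 to 15.5, the controls at -20.6 to 0.840 and the double KO livers at -8.05 to 2.78.

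Few single genes differed in SMRT KO livers. In SMRT KO against control livers, 1 of 22180 genes passed an adjusted p of 0.05. This gene, Elapor1, which encodes a membrane protein of the endosome and lysosome system, rose 2.06-fold, from 6.26 ± 0.147 in control to 7.30 ± 0.0829 in SMRT KO livers (log2 values, SD, n = 3 each). Its log2 fold change was 1.04 with a standard error of 0.0839 and an adjusted p of 0.00874. The call was lost without SMRT KO replicate 1 (adjusted p = 0.083), without SMRT KO replicate 3 (0.0706) and with only the 2 groups in the fit (0.296), in a range of 0.00446 to 0.296 over 18 alternatives. At an unadjusted p under 0.05 limma counted 1331 genes, where 1109 would be expected by chance. The 3 values of each group did not overlap in 8.16% of genes, against 10% by chance. The count of called genes was 0 without SMRT KO replicate 1 or 3, 2 without SMRT KO replicate 2, and 3, 23 and 5 without control replicates 1, 2 and 3.

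The thyroid hormone-responsive genes fixed for every comparison did not pass in SMRT KO livers. Thrsp, a regulator of lipid synthesis, had a log2 fold change of 0.05 (standard error 0.380, adjusted p = 0.995), Me1, which makes NADPH for that pathway, -0.20 (adjusted p = 0.933), and Fasn, the fatty acid synthase, -0.03 (adjusted p = 0.991). Dio1, the deiodinase that activates thyroid hormone, had -0.80 with a standard error of 0.266 and a 95% interval of -1.39 to -0.20, at an adjusted p of 0.753. The higher genes with the smallest p after Elapor1, none of which passed, were Ulk2 (log2 fold change 0.55, adjusted p = 0.0894), Nlrp1c-ps (1.48, 0.0924), Cyp26a1 (2.47, 0.194) and Angptl8 (0.76, 0.194). Cyp26a1, which degrades retinoic acid, was 5.53-fold higher in the mean, from 7.34 ± 0.941 to 9.81 ± 0.318, and passed without control replicate 3 (adjusted p = 0.00269, range 0.00269 to 0.583 over the alternatives). The lower genes were Mup-ps12 (-2.16), Krtap4-8 (-0.67), Vmn2r57 (-0.998), Olfr819 (-0.47) and Xaf1 (-0.58), all at an adjusted p of 0.0924. The control mean of Nlrp1c-ps (3.88) and the SMRT KO means of Krtap4-8 (3.97) and Vmn2r57 (3.69) lay near the medians of olfactory and vomeronasal receptor genes, 3.73 to 4.13 over the arrays, and are not shown to be above background. Of these genes, Ulk2, Olfr819 and Xaf1 passed without control replicate 2 (adjusted p = 0.0371, 0.0331 and 0.0331) and Mup-ps12 without SMRT KO replicate 2 (0.00184). Ulk2 also passed with the dimmest genes left out. Their highest adjusted p over the alternatives was 0.429 for Ulk2, 0.471 for Olfr819 and Xaf1, and 0.472 for Mup-ps12.

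Markers of immune cells and of proliferation were slightly higher as groups in SMRT KO livers, and thyroid hormone-induced and cholesterol genes slightly lower, by camera with its preset correlation. All 17 Kupffer cell and macrophage markers had a fold change above 0, with a median log2 fold change of 0.17 (adjusted p = 3.2e-07; adjusted p = 0.222 with an estimated correlation), among them Adgre1 (0.35), C1qb (0.33) and Cd5l (0.33). The 17 cell cycle genes had a median of 0.13 (adjusted p = 1.33e-05; adjusted p = 0.258 with an estimated correlation), with Ccnb2 at 0.52 and Cdk1 at 0.47. The 10 lymphocyte markers had a median of 0.15 (adjusted p = 0.000813; adjusted p = 0.349 with an estimated correlation) and the 12 endothelial markers 0.09 (adjusted p = 0.0216; adjusted p = 0.732 with an estimated correlation). The 17 measured thyroid hormone-induced genes had a median of -0.15 (adjusted p = 0.00672; adjusted p = 0.319 with an estimated correlation), with 3 of them above 0. The 19 cholesterol synthesis and uptake genes had a median of -0.10 (adjusted p = 0.0255; adjusted p = 0.733 with an estimated correlation). The members named here were chosen after their values were seen, and 0 members of any of the 6 lists passed limma's test over all genes. Adjusted over the list alone, 1 macrophage, 1 lymphocyte and 1 endothelial marker and 1 bile acid gene passed, and 2 genes each of the lipid droplet, female-biased and NRF2 lists. By fry, 0 of the 27 lists passed.

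Some of these list calls were lost when 1 mouse was left out. Such fits have fewer mice, so a call can be lost with little change in the median. SMRT KO replicate 3 had low values of Dio1 (9.67) and Me1 (10.01). Its Thrsp value was 9.10, but Thrsp varied about as widely among control (9.79 ± 0.684, SD) as among SMRT KO livers (9.84 ± 0.711). Without SMRT KO replicate 3 the thyroid hormone-induced list had a median of -0.05 at an adjusted p of 0.26, in a range of 0.000145 to 0.319 over its alternatives. The lymphocyte call was also lost without that mouse (adjusted p = 0.0826), the cholesterol call without it or without control replicate 2 or 3 (0.237, 0.259 and 0.566) and after cyclic loess (0.0534), and the endothelial call without SMRT KO replicate 1 or 3 or control replicate 1 (0.0786, 0.11 and 0.305). In these fits the lymphocyte median was 0.12 without SMRT KO replicate 3, against 0.15 with all mice. The cholesterol median was -0.07 without SMRT KO replicate 3 and -0.05 and -0.01 without control replicates 2 and 3. The endothelial median, 0.09 with all mice, was 0.08 and 0.09 without SMRT KO replicates 1 and 3 and 0.02 without control replicate 1. The macrophage and cell cycle calls held in all 9 fits that left out 1 mouse.

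**Figure D1:**
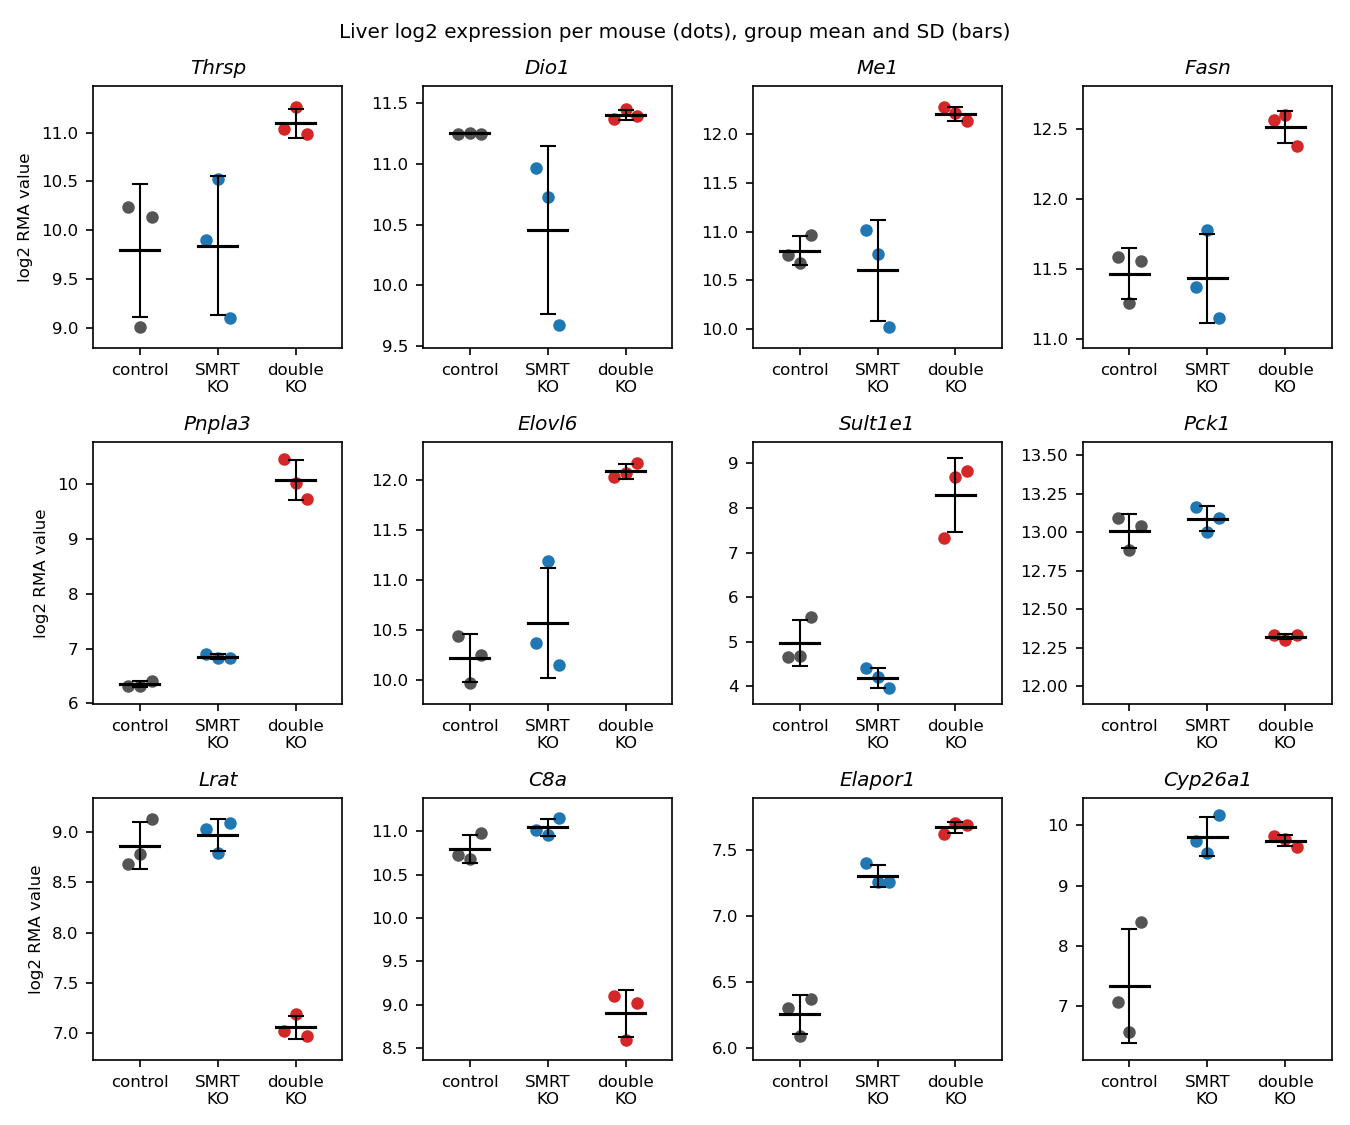
Log2 RMA expression of 12 genes in the liver of each mouse (y axis, with its own scale per gene) by group (x axis: control, SMRT KO, double KO). Dots are mice, the wide bar is the mean of 3 and the error bar its SD; the 3 double KO livers lie above both other groups for Pnpla3, Elovl6 and Sult1e1 and below them for Pck1, Lrat and C8a.

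More genes differed in double KO livers. In double KO against control livers 116 genes rose and 71 fell, 187 of 22180, of which 63 changed at least 2-fold (48 higher and 15 lower). Pnpla3, a lipase-family protein of lipid droplets, rose 13.2-fold, from 6.35 ± 0.0539 to 10.1 ± 0.366 (log2 values, SD, n = 3 each; log2 fold change 3.72, standard error 0.150, adjusted p = 1.66e-05). Among the 5 largest rises were also the sulfotransferases Sult2a3 (15.3-fold, adjusted p = 0.00508), Sult1e1, which sulfates estrogens (10.01-fold, 0.0054), and Sult2a7 (8.45-fold, 0.00304), together with the steroid dehydrogenase Akr1c18 (9.36-fold, 0.00106). The largest falls were in Cyp2d9, a male-biased cytochrome P450 (4.003-fold lower, adjusted p = 0.00357), C8a, a complement component (3.72-fold lower, 0.000397), Lrat, which esterifies retinol for storage (3.49-fold lower, 0.000397), the urinary protein gene Mup21 (3.39-fold lower, 0.0276) and Sdr9c7 (2.84-fold lower, 0.0346). Sult2a7 in control (mean 4.04) and Mup21 in double KO livers (3.74) lay near the same receptor medians, so the size of their folds rests on values not shown to be above background. Groups did not overlap in 14.98% of all genes, against 10% by chance, and in all 187 called genes. The count was 91 without control replicate 1, 83 without control replicate 3, and 90, 61 and 91 without double KO replicates 1, 2 and 3. Of the 10 genes just named, 8 kept their calls in all 9 fits that left out 1 mouse. The call of Mup21 was lost without each control and each double KO mouse (adjusted p up to 0.118), and that of Sdr9c7 without each SMRT KO mouse, control replicates 2 and 3 and double KO replicates 1 and 2 (up to 0.136).

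The thyroid hormone-induced genes split in double KO livers. Of 17 measured members 4 rose, 1 fell and 12 did not pass, and adjusted over the list alone 6 rose and 1 fell. Me1 rose 2.66-fold (log2 fold change 1.41, standard error 0.213, adjusted p = 0.0195), Fasn 2.06-fold (adjusted p = 0.0184), Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, 1.93-fold (0.00692) and Gpd2, a mitochondrial glycerol phosphate dehydrogenase, 1.84-fold (0.0346). Pck1, the enzyme that commits carbon to glucose production, fell by 0.68 on the log2 scale (adjusted p = 0.00395). Thrsp had a log2 fold change of 1.30 with a standard error of 0.380 and did not pass (adjusted p = 0.217), and Dio1 had 0.15 (standard error 0.266, adjusted p = 0.895). The list as a whole was higher (median 0.30, adjusted p = 0.00169; adjusted p = 0.266 with an estimated correlation). Me1, Fasn, Acaca and Thrsp are also members of the fatty acid and triglyceride synthesis list, and Pck1 of the glucose list. The results of these lists are therefore not separate findings. Called members of the thyroid hormone-induced list numbered 2 without each of the 3 control and the 3 double KO mice. The calls of Me1 and Fasn were lost without each of these 6 mice, with adjusted p up to 0.0942 for both genes, and that of Gpd2 without them or SMRT KO replicate 2, with values up to 0.133.

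Fatty acid and triglyceride synthesis genes were higher as a group by camera with its preset correlation. Of 25 measured members 8 rose, 0 fell and 17 did not pass over all genes, and adjusted over the list alone 18 rose and 2 fell. Elovl6, which lengthens fatty acids, rose 3.66-fold (adjusted p = 0.00821) and Acacb, the carboxylase at mitochondria, 2.48-fold (0.0182), beside Pnpla3 and Me1 above. The list's median log2 fold change was 0.56 (adjusted p = 9.36e-18; adjusted p = 0.0543 with an estimated correlation). Called members numbered 4 and 5 without control replicates 1 and 2, and 3, 3 and 4 without double KO replicates 1, 2 and 3. The call of Acacb was lost without 4 of the 9 mice (control replicate 1 and each double KO mouse), with adjusted p up to 0.0942.

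Lipid storage, fatty acid oxidation and LXR target genes were also higher as groups in double KO livers. The LXR list shares Lpl with the storage list and Scd1 and Srebf1 with the synthesis list, so their results overlap. Of 19 lipid droplet and storage genes 5 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.26, adjusted p = 1.12e-06; adjusted p = 0.113 with an estimated correlation). They included Lpl, which releases fatty acids from lipoproteins (3.49-fold, adjusted p = 0.0108), the fatty acid transporter Cd36 (2.48-fold, 0.00309), Fitm1 (2.07-fold, 0.0276) and Plin2, a droplet coat protein (1.56-fold, 0.016). The fifth was Pparg (log2 fold change 0.52, adjusted p = 0.0346), chosen after its values were seen. Other probe sets of Lpl and Fitm1, with lower means, gave log2 fold changes of 0.37 and 0.19 against 1.80 and 1.052. Of 32 fatty acid oxidation and ketogenesis genes 5 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.14, adjusted p = 6.24e-06; adjusted p = 0.529 with an estimated correlation), among them Pdk4, which restrains glucose oxidation (5.13-fold, adjusted p = 0.0281), the acyl-CoA thioesterases Acot1 (4.01-fold, 0.00357) and Acot2 (2.71-fold, 0.0054), and the peroxisomal Ehhadh (3.02-fold, 0.00357). Acaa1b was the fifth (log2 fold change 1.34, adjusted p = 0.0114), chosen after its values were seen. Of 14 LXR targets 5 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.38, adjusted p = 1.48e-07; adjusted p = 0.113 with an estimated correlation). Besides Lpl these were Pltp, a phospholipid transfer protein (4.31-fold, adjusted p = 0.00304), Scd1, the stearoyl-CoA desaturase (1.63-fold, 0.0195), the sterol transporter Abcg5 (1.47-fold, 0.0263) and Lpcat3 (log2 fold change 0.53, adjusted p = 0.0367), chosen after its values were seen.

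These 3 counts varied with the mice in the fit. Called lipid droplet members numbered 3 without SMRT KO replicate 1 or control replicate 1, 2 without control replicate 3, and 2, 2 and 1 without double KO replicates 1, 2 and 3. Called fatty acid oxidation members numbered 3 without each double KO mouse. Called LXR targets numbered 2, 3 and 2 without control replicates 1, 2 and 3 and 3, 1 and 1 without double KO replicates 1, 2 and 3. Cd36, Acot1, Acot2, Ehhadh and Pltp kept their calls in all 9 fits that left out 1 mouse, and the 3 list calls held in them too. The call of Pparg held only without control replicate 2 (adjusted p up to 0.158) and that of Lpcat3 only without double KO replicate 1 (up to 0.136). Those of Acaa1b (up to 0.061), Fitm1 (0.112), Pdk4 (0.12), Scd1 (0.0942) and Abcg5 (0.127) were lost without each double KO mouse, that of Lpl without double KO replicates 2 and 3 (0.067) and that of Plin2 without double KO replicates 1 and 3 (0.0694). Calls were also lost without control replicate 1 for Pdk4, Scd1, Abcg5 and Plin2, control replicate 2 for Fitm1 and Scd1, and control replicate 3 for Fitm1, Plin2, Pdk4, Scd1 and Abcg5. Fitm1 lost its call without SMRT KO replicate 1 as well, and Pdk4 without SMRT KO replicate 3.

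By camera with its preset correlation, xenobiotic metabolism genes and NRF2 targets were higher as groups, and glucose genes lower. The xenobiotic and NRF2 lists share Gstm1, Gstm3 and Nqo1, so their results are not separate findings. Of 22 xenobiotic metabolism genes 4 rose and 1 fell (10 and 3 adjusted over the list alone; median 0.32, adjusted p = 4.16e-06; adjusted p = 0.117 with an estimated correlation). Besides Sult1e1, the glutathione transferase Gstm3 rose 4.47-fold (adjusted p = 0.0054) and the cytochromes P450 Cyp3a25 2.72-fold (0.00395) and Cyp3a11 1.39-fold (0.0251), while Cyp1a2, chosen after its values were seen, fell by 0.41 on the log2 scale (adjusted p = 0.0239). Of 14 NRF2 targets 2 rose and 0 fell (5 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.000813; adjusted p = 0.266 with an estimated correlation), namely Gstm3 and the organic anion exporter Abcc4 (4.13-fold, adjusted p = 0.000147). Abcc4 was also the 1 called member among 23 bile acid genes, a list that did not pass camera (median 0.02, adjusted p = 0.547) and passed by fry (higher, adjusted p = 0.0465). Of 14 glucose genes 1 rose and 2 fell (2 and 5 adjusted over the list alone; median -0.23, adjusted p = 0.00221; adjusted p = 0.235 with an estimated correlation). Pck1 and Gys2, the liver glycogen synthase (1.63-fold lower, adjusted p = 0.0214), fell, and the riser was Pdk4, which does not make glucose. Called xenobiotic genes numbered 3 without each double KO mouse, and called glucose genes 1 without control replicate 1 or 3 or double KO replicate 1 or 2. The calls of Cyp3a11 (adjusted p up to 0.124) and Cyp1a2 (0.0983) were lost without each double KO mouse and control replicate 3, Cyp3a11 also without control replicate 2 and Cyp1a2 without control replicate 1. That of Gys2 was lost without control replicates 1 and 3 and double KO replicates 1 and 2 (up to 0.0878).

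Among sex-biased genes and cell type markers, the male-biased, hepatocyte and adipocyte lists were lower in double KO livers. Of 17 male-biased genes 1 fell, Cyp2d9, and 0 rose (5 and 1 adjusted over the list alone; median -0.24, adjusted p = 0.0269; adjusted p = 0.648 with an estimated correlation). That list call was lost without control replicate 3 (median -0.10, adjusted p = 0.143), double KO replicate 1 (-0.15, 0.0772) or double KO replicate 2 (-0.20, 0.2). Called members numbered 2 without SMRT KO replicate 1 or control replicate 1. Of 13 female-biased genes 1 rose, the sulfotransferase Sult2a1 (2.83-fold, adjusted p = 0.00835), chosen after its values were seen, and the list did not pass (median 0.19, adjusted p = 0.103). The call of Sult2a1 was lost without double KO replicate 2 (0.0565), and the female-biased list passed without control replicate 1 (median 0.38, adjusted p = 0.0252). Of 10 hepatocyte markers 0 rose and 1 fell, Serpina1a (1.38-fold lower, adjusted p = 0.0251), with 0 and 2 adjusted over the list alone and a list median of -0.07 (adjusted p = 0.0121; adjusted p = 0.373 with an estimated correlation). Of 8 adipocyte markers 0 rose and 1 fell, the carbonic anhydrase Car3 (1.35-fold lower, adjusted p = 0.0346), with 0 and 2 adjusted over the list alone and a median of -0.14 (adjusted p = 0.0237; adjusted p = 0.222 with an estimated correlation). Both list calls were lost without control replicate 2 (adjusted p = 0.0947 and 0.144), with a median of -0.05 for hepatocyte and -0.07 for adipocyte markers. The hepatocyte call was also lost after cyclic loess (0.0595). The call of Serpina1a was lost without control replicates 1 and 2 and each double KO mouse (up to 0.116). The call of Car3 held only without double KO replicate 3 (up to 0.14). Lrat was the 1 called gene of 14 stellate cell and matrix markers (list median -0.05, adjusted p = 0.0774). That list passed, lower, without double KO replicate 2 (median -0.21, adjusted p = 0.000545), control replicate 1 (-0.16, 0.0122) or control replicate 3 (-0.09, 0.0334).

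**Figure D2:**
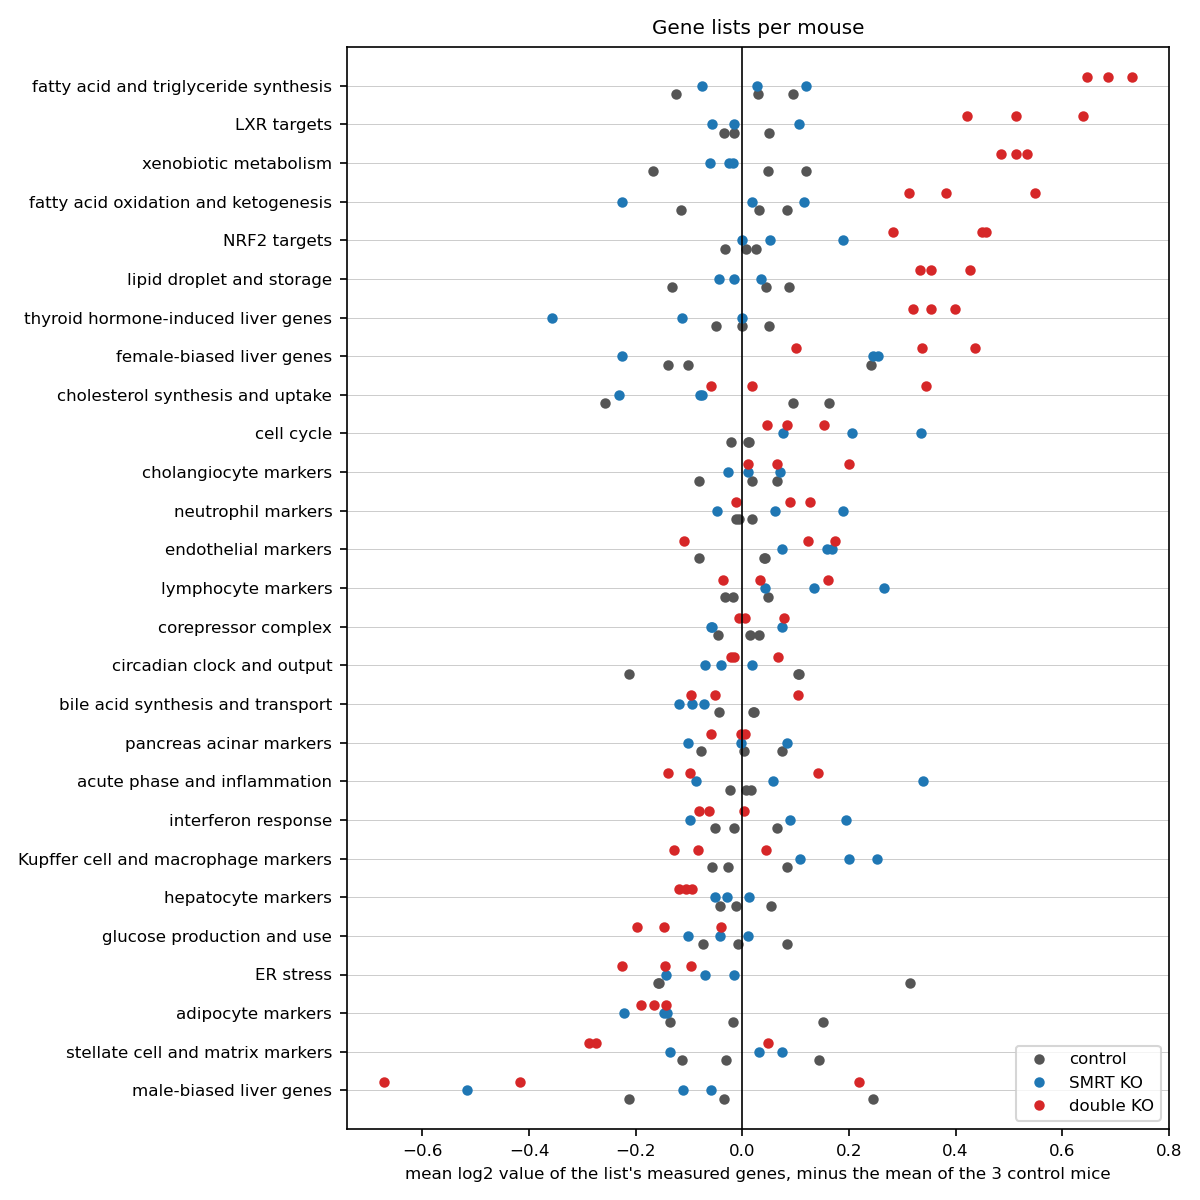
Mean log2 value of the measured genes of each of the 27 tested lists in each mouse, minus the mean of the 3 control mice (x axis, log2), with 1 line per list (y axis) and 1 dot per mouse, coloured by group. The 3 double KO livers lie above all control and SMRT KO livers for fatty acid and triglyceride synthesis, LXR targets, xenobiotic metabolism, NRF2 targets and thyroid hormone-induced genes.

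Set against SMRT KO livers, the double KO livers differed in 263 genes, 166 higher and 97 lower, with 74 at least 2-fold (50 higher and 24 lower). This comparison adds the loss of NCoR1 to that of SMRT, and cannot separate it from a difference in genetic background between the groups. Sult1e1 was 17.15-fold higher (log2 fold change 4.10, standard error 0.385, adjusted p = 0.00204) and Pnpla3 9.32-fold higher (adjusted p = 6.3e-05), followed by Sult2a3 (7.90-fold, 0.0148), the pseudogene Mup-ps12 (7.73-fold, 0.00204) and Elovl3, another fatty acid elongase (7.43-fold, 0.0473). The SMRT KO mean of Sult1e1, 4.19, was near the same receptor medians, and the size of its fold is as uncertain. Lower genes were Serpina7, which encodes thyroxine-binding globulin (4.55-fold, adjusted p = 0.0113), Etnppl, a phospholyase (4.51-fold, 0.00367), C8a (4.42-fold, 0.000351), the imprinted RNA Rian (4.004-fold, 0.0147) and Cyp2d9 (3.94-fold, 0.00339). Serpina7 stood at 8.70 ± 0.700 in control, 10.3 ± 0.261 in SMRT KO and 8.07 ± 0.286 in double KO livers (log2 values, SD, n = 3 each), and neither knockout passed against control (adjusted p = 0.326 and 0.508). Groups did not overlap in 13.8% of all genes, against 10% by chance. The count was 124 and 169 without SMRT KO replicates 1 and 2, and 158, 101 and 152 without double KO replicates 1, 2 and 3. The calls of Sult2a3 and Rian were lost without SMRT KO replicate 1 or double KO replicate 1 or 2 (adjusted p up to 0.0823 and 0.0815) and that of Serpina7 without SMRT KO replicate 1 or double KO replicate 3 (up to 0.0559). That of Elovl3 held only in the fits without control replicate 1 and without SMRT KO replicate 1, with values up to 0.158.

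Thyroid hormone-induced and lipid synthesis genes were higher as groups in double KO than in SMRT KO livers. These lists share Me1, Fasn, Acaca and Thrsp, so their results are not separate findings. Of the 17 thyroid hormone-induced genes 5 were higher and 1 lower (10 and 1 adjusted over the list alone; median 0.58, adjusted p = 3.2e-07; adjusted p = 0.117 with an estimated correlation). Me1 was 3.06-fold higher (adjusted p = 0.00809), Gpd2 2.18-fold (0.00875), Fasn 2.11-fold (0.0129) and Acaca 2.10-fold (0.00354), Pck1 was 1.70-fold lower (0.00219), and the remaining call was Abcd3 (log2 fold change 0.67, adjusted p = 0.0197), a peroxisomal transporter chosen after its values were seen. Dio1 had a log2 fold change of 0.95 (standard error 0.266, adjusted p = 0.179) and passed without SMRT KO replicate 3 (adjusted p = 0.025, range 0.025 to 0.406 over the alternatives), and Thrsp had 1.26 (standard error 0.380, adjusted p = 0.226). Of 25 fatty acid and triglyceride synthesis genes 8 were higher and 0 lower (17 and 1 adjusted over the list alone; median 0.49, adjusted p = 3.04e-17; adjusted p = 0.0543 with an estimated correlation), with Acacb at 3.10-fold (adjusted p = 0.0052) and Elovl6 at 2.86-fold (0.0168). Called members of that list numbered 5 without SMRT KO replicate 1 and 4, 4 and 5 without double KO replicates 1, 2 and 3. Me1, Gpd2, Acaca, Acacb and Pck1 kept their calls in all 9 fits that left out 1 mouse, and Me1 lost its call with only the 2 groups in the fit (adjusted p = 0.0504, the highest over its alternatives). Those of Fasn and Elovl6 were lost without SMRT KO replicate 1 and double KO replicates 1 and 2 (adjusted p up to 0.071 and 0.0823), Elovl6 also without double KO replicate 3, and that of Abcd3 without each double KO mouse (up to 0.0939).

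The other lipid lists were higher as well. As above, the LXR list shares members with the storage and synthesis lists. Of 19 lipid droplet genes 2 were higher, Lpl (3.08-fold, adjusted p = 0.014) and Plin2 (1.84-fold, 0.00323), and 0 lower (9 and 0 adjusted over the list alone; median 0.38, adjusted p = 1.48e-07; adjusted p = 0.113 with an estimated correlation). Of 32 fatty acid oxidation genes 5 were higher and 0 lower (10 and 0 adjusted over the list alone; median 0.27, adjusted p = 7.97e-09; adjusted p = 0.349 with an estimated correlation), namely Pdk4 (5.21-fold, adjusted p = 0.0229), Acot1 (3.14-fold, 0.007), Ehhadh (3.11-fold, 0.00279), the peroxisomal thiolase Acaa1b (2.74-fold, 0.0061) and Acot2 (log2 fold change 1.11, 0.0147), the last chosen after its values were seen. Of 14 LXR targets 5 were higher and 0 lower (7 and 0 adjusted over the list alone; median 0.41, adjusted p = 1.48e-07; adjusted p = 0.113 with an estimated correlation): Pltp (4.50-fold, adjusted p = 0.0021), Lpl, Scd1 (1.56-fold, 0.024), Lpcat3 (1.47-fold, 0.0237) and Abcg5 (log2 fold change 0.50, 0.0343), the last chosen after its values were seen. Of 19 cholesterol genes 1 was higher, Tm7sf2 (1.54-fold, adjusted p = 0.0243), and 0 lower (1 and 0 adjusted over the list alone; median 0.23, adjusted p = 0.000611; adjusted p = 0.648 with an estimated correlation), and that list call was lost without double KO replicate 2 (adjusted p = 0.152). The cholesterol list median was 0.08 without double KO replicate 2. Called lipid droplet members numbered 1 without SMRT KO replicate 1 or double KO replicate 2 or 3 and 4 without control replicate 1. Called fatty acid oxidation members numbered 3 without SMRT KO replicate 3 or double KO replicate 2. Called LXR targets numbered 1 and 2 without SMRT KO replicates 1 and 2, and 3, 1 and 2 without double KO replicates 1, 2 and 3. Plin2, Acot1, Ehhadh, Acaa1b and Pltp kept their calls in all 9 fits that left out 1 mouse. Without SMRT KO replicate 1 the calls of Lpl, Acot2, Tm7sf2, Scd1, Lpcat3 and Abcg5 were lost, without SMRT KO replicate 2 those of Pdk4, Tm7sf2, Scd1, Lpcat3 and Abcg5, and without SMRT KO replicate 3 those of Pdk4, Acot2, Tm7sf2 and Abcg5. Without double KO replicate 1 those of Scd1 and Abcg5 were lost, without double KO replicate 2 all 7 of these, without double KO replicate 3 those of Lpl, Tm7sf2, Scd1 and Abcg5, and without control replicate 3 that of Abcg5. Their highest adjusted p was 0.0785 for Lpl, 0.0573 for Acot2, 0.076 for Pdk4, 0.113 for Tm7sf2, 0.108 for Scd1, 0.0826 for Lpcat3 and 0.141 for Abcg5.

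The xenobiotic, NRF2 and bile acid lists were higher as well, and the glucose list lower. The NRF2 list shares Gstm1, Gstm3 and Nqo1 with the xenobiotic list and Abcc4 with the bile acid list, so these are not separate findings. Of 22 xenobiotic genes 3 were higher and 1 lower (6 and 1 adjusted over the list alone; median 0.21, adjusted p = 6.56e-05; adjusted p = 0.162 with an estimated correlation), with Gstm3 3.91-fold and Cyp3a25 2.55-fold higher (adjusted p = 0.0069 and 0.00458) and Cyp1a2 1.31-fold lower (0.0259). Of 14 NRF2 targets 3 were higher and 1 lower (6 and 1 adjusted over the list alone; median 0.12, adjusted p = 0.00366; adjusted p = 0.319 with an estimated correlation). Abcc4 was 2.61-fold higher (adjusted p = 0.00186), Osgin1 1.85-fold higher (0.024) and Gclc, a subunit of the glutathione-making ligase, 1.60-fold lower (0.0411). Of 23 bile acid genes 1 was higher, Abcc4, and 0 lower (3 and 1 adjusted over the list alone; median 0.18, adjusted p = 0.00915; adjusted p = 0.14 with an estimated correlation). Of 14 glucose genes 2 were higher and 2 lower (2 and 6 adjusted over the list alone; median -0.25, adjusted p = 0.0212; adjusted p = 0.319 with an estimated correlation). Pdk4 and the glycogen phosphorylase Pygl (1.33-fold, adjusted p = 0.0328) were higher, and Pck1 and Gys2 (1.53-fold, 0.0327) lower. Without double KO replicate 1 the glucose list did not pass (adjusted p = 0.0772). Called glucose genes numbered 2 without each SMRT KO mouse or double KO replicate 1 and 1 without double KO replicate 2, and called NRF2 targets 2 without each SMRT KO mouse or double KO replicate 3. Called bile acid genes numbered 2 without control replicate 1 or double KO replicate 3. The call of Gclc held only without double KO replicate 1 (adjusted p up to 0.153), and those of Cyp1a2, Osgin1, Gys2 and Pygl were lost without each SMRT KO mouse (up to 0.0937, 0.0995, 0.123 and 0.126). Those of Cyp1a2 and Pygl were also lost without each double KO mouse, that of Osgin1 without double KO replicates 1 and 3, and that of Gys2 without double KO replicates 1 and 2 and control replicate 3. The other genes of this paragraph except Pdk4 kept their calls.

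Macrophage markers, the cell cycle and hepatocyte markers were lower as groups in double KO than in SMRT KO livers. The 17 macrophage markers had a median log2 fold change of -0.23 (adjusted p = 1.29e-06; adjusted p = 0.235 with an estimated correlation), with 0 called members over all genes and 5 lower adjusted over the list alone. The 17 cell cycle genes had a median of -0.12 (adjusted p = 0.0269; adjusted p = 0.631 with an estimated correlation) and the 10 hepatocyte markers -0.04 (adjusted p = 0.0269; adjusted p = 0.486 with an estimated correlation), with 0 called members each. The cell cycle call was lost without SMRT KO replicate 2 or double KO replicate 2 or 3 (adjusted p = 0.423, 0.0764 and 0.112) and with the dimmest genes left out (0.0903), and the hepatocyte call without SMRT KO replicate 3 or double KO replicate 3 (0.137 and 0.0694) and after cyclic loess (0.0534). Against control, the macrophage list did not pass in double KO livers (adjusted p = 0.547). Of 17 male-biased genes 1 was higher, Elovl3, and 2 lower, Cyp2d9 and Susd4 (1.68-fold, adjusted p = 0.0183), and the list did not pass (adjusted p = 0.506), with a median of 0.10 and a mean of -0.06. Called male-biased genes numbered 1 without SMRT KO replicate 2 or 3 or double KO replicate 2, and the call of Susd4 was lost without each SMRT KO mouse and double KO replicates 2 and 3 (adjusted p up to 0.0939). Single calls in lists that did not pass were Sult2a1 (log2 fold change 1.04, adjusted p = 0.0357), Lrat (-1.91, 0.000391), Car3 (-0.58, 0.007) and the clock gene Per1 (-0.78, 0.0277), all chosen after their values were seen. Those of Lrat and Car3 held in all 9 fits that left out 1 mouse, and those of Sult2a1 and Per1 held only without control replicates 1 and 2, with adjusted p up to 0.146 and 0.125.

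Of the 35 named calls against control in double KO livers 19 held in all 9 fits that left out 1 mouse, and of the 36 against SMRT KO livers 19 did. The highest adjusted p among those lost was 0.14 and 0.158. These counts leave out the 14 values of genes chosen after they were seen. With only the 2 groups in the fit 9 and 14 of the named calls were lost, and of these Me1 against SMRT KO was the 1 that had held without each mouse. Against control, 12, 10 and 13 named calls were lost without control replicates 1, 2 and 3 and 15, 15 and 13 without double KO replicates 1, 2 and 3. Against SMRT KO, 15, 11 and 9 were lost without SMRT KO replicates 1, 2 and 3 and 10, 15 and 11 without double KO replicates 1, 2 and 3.

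The 2 knockouts shared 1 called gene against control, Elapor1, which rose in both. In double KO livers it rose 2.66-fold against control, to 7.67 ± 0.0408 (adjusted p = 0.000147). In 100 simulations of unchanged groups set against the same controls 0 genes were shared, a count held near 0 because unchanged groups give almost no calls. Independent lists of these sizes, which leave out the shared controls, would share 0.00523. Cyp26a1 rose 5.28-fold in double KO livers (adjusted p = 0.0239), a gene chosen for this comparison after its values were seen, and its call was lost without control replicate 1 or any double KO mouse (adjusted p up to 0.112). Its difference between the knockouts was -0.07 on the log2 scale (adjusted p = 0.979). Of the 187 genes called in double KO livers 110, or 58.8%, had the same sign in SMRT KO livers, against 54.7% (41.9% to 63.8%) in 100 simulations with the changes of the 187 genes in double KO and none in SMRT KO livers. Their median SMRT KO shift in the direction of the double KO call was 0.0404 on the log2 scale, against 0.0103 (-0.0175 to 0.0366). Across genes, which are not independent replicates, the 2 sets of log2 fold changes against control had a correlation of 0.39, against 0.50 (0.44 to 0.61) in the simulations of unchanged groups. Their covariance was 0.0121 against 0.00945 (0.00842 to 0.0143), a difference of 0.00266. The same-sign share and the covariance lay within the range of the simulations, the correlation below it and the median shift above it. The correlation was simulated with no change in double KO livers. Changes in double KO livers alone lower a correlation, so its low value does not show that the knockouts are less alike. The simulated groups shared their controls as well, but their genes varied independently, which real genes do not, so the simulated ranges may be too narrow. The 3 controls were not split into smaller sets. Part of the excess in the median shift may therefore still come from the shared controls.

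**Figure D3:**
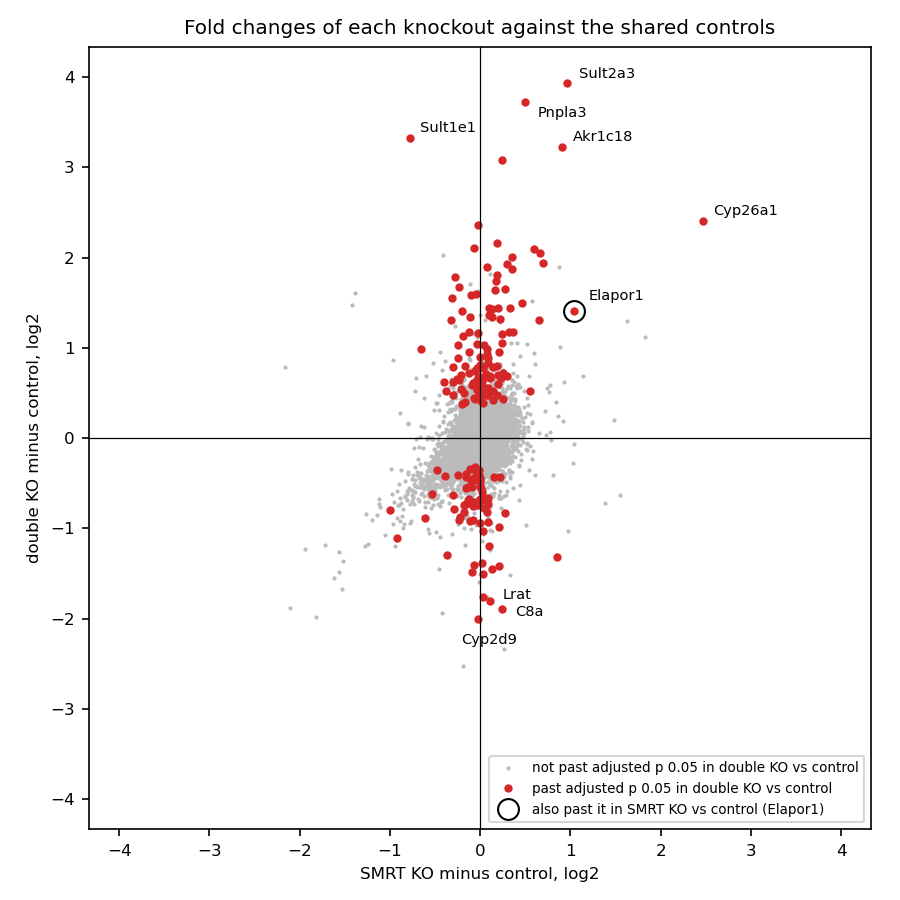
Log2 fold change of each of the 22180 genes in SMRT KO against control (x axis) and in double KO against control (y axis), both relative to the same 3 control livers. Each dot is a gene, red dots are the 187 genes called in double KO livers, and the circle marks Elapor1, the 1 gene called in both.

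The other lists did not pass in any comparison under the main settings. Their lowest adjusted p over the 3 comparisons was 0.712 for the 11 measured members of the corepressor complex, 0.728 for the 19 circadian genes, 0.103 for the female-biased genes, 0.079 for the 14 ER stress genes, 0.079 for the 19 acute phase genes and 0.0748 for the 12 interferon response genes. It was 0.0774 for the stellate cell, 0.407 for the 6 cholangiocyte, 0.127 for the 8 neutrophil and 0.903 for the 8 pancreatic acinar markers. Some of these lists passed camera when 1 mouse was left out. Without SMRT KO replicate 1, interferon (adjusted p = 0.00104) and acute phase genes (0.00214) were lower in double KO than in SMRT KO livers. Without control replicate 1, ER stress genes were lower in double KO than in control livers (0.00755). Circadian genes were lower in SMRT KO livers without control replicate 2 (0.01), and neutrophil markers higher without SMRT KO replicate 1 (0.0183). The 1 measured erythroid marker, Slc4a1, had log2 fold changes of 0.08 and 0.09 in SMRT KO and double KO livers against control. The lists that passed in a comparison were 6, 11 and 13 of 27, and the others had adjusted p of 0.0615 to 0.952 in SMRT KO against control, 0.0774 to 0.974 in double KO against control and 0.0748 to 0.947 in double KO against SMRT KO. By fry, 7 of the 11 lists that passed in double KO against control passed as well, and thyroid hormone-induced genes (adjusted p = 0.0578), fatty acid oxidation (0.159), male-biased genes (0.418) and hepatocyte markers (0.0537) did not. In double KO against SMRT KO 7 of 13 did, and fatty acid oxidation (0.0795), cholesterol (0.424), glucose (0.0578), cell cycle (0.435), hepatocyte (0.0956) and macrophage genes (0.0782) did not. Median, mean and test differed in sign for xenobiotic, stellate and cholangiocyte genes in SMRT KO against control and for bile acid, circadian, acute phase and pancreatic genes in double KO against control. They also differed for corepressor, circadian, male-biased, neutrophil, pancreatic and adipocyte genes in double KO against SMRT KO, and none of these lists passed there.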

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

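The test of probe sets that carry no single gene name was chosen after the named genes had been examined. It covered the 17634 probe sets outside the tested genes, control probe sets left out, with the same limma model and adjustment. In double KO against control livers 1 of them passed, and in double KO against SMRT KO livers 7 passed, all of them higher in double KO. In SMRT KO against control 0 passed by limma, with 1054 at an unadjusted p under 0.05. The probe set that passed against control, 17457158, had a log2 fold change of 2.22 (standard error 0.198, adjusted p = 0.0494), with 3.64, 3.90 and 3.90 in the control livers and 5.96, 6.39 and 5.76 in the double KO livers. Its control values lie near the medians of olfactory and vomeronasal receptor genes (3.73 to 4.13 over the arrays) and are not shown to be above background, so the size of the change is uncertain. Against SMRT KO, probe set 17231571 had 3.99 (adjusted p = 0.0312) and probe set 17414520 had 2.50 (adjusted p = 0.00622). The latter stood at 10.16 in each of the 3 control livers, at 7.96 to 8.67 in the SMRT KO livers and at 10.65 to 10.94 in the double KO livers. The genes these probe sets measure are not analysed here, no fit left out single mice for them, and no explanation was tested.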

How the results depend on the processing

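Cyclic loess normalization and the fit without the genes nearest Ncor1 were chosen after the results were seen, and the other alternatives were planned. None of the 1, 187 and 263 called genes changed sign in the 18 alternatives run for single genes, and none of the 30 list results in those run for lists.

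The 1 gene called in SMRT KO against control became 2 with the dimmest 40% of genes left out, which tests fewer genes, 0 with only the 2 groups in the fit, which rests on fewer arrays, and 8 at an adjusted p of 0.10. Leaving out 1 mouse gave 0 to 23 genes. The 187 genes called in double KO against control became 109 with only the 2 groups, 285 with array weights (the cause was not tested) and 327 at an adjusted p of 0.10, and leaving out 1 mouse gave 61 to 179. The 263 genes of double KO against SMRT KO became 124 with only the 2 groups and 435 at an adjusted p of 0.10, and leaving out 1 mouse gave 101 to 234. The 1 gene shared by both knockouts became 4 at an adjusted p of 0.10 and 0 to 17 when 1 mouse was left out. Under the other alternatives, the replicate block apart, these counts stayed within 1.5 times the main value, with 202 and 297 genes after cyclic loess and 187 and 253 without the genes nearest Ncor1 for double KO against control and against SMRT KO. The 30 list results became 0 with an estimated correlation, 15 by fry, of which 14 were among the 30 and 1 was the bile acid list in double KO against control, 32 without dim genes and 27 after cyclic loess. They numbered 25 to 38 when 1 mouse was left out. The calls that cyclic loess ended were those of cholesterol genes in SMRT KO against control and of hepatocyte markers in double KO against either other group. Leaving out dim genes ended the cell cycle call in double KO against SMRT KO (adjusted p = 0.0903) and added bile acid genes (0.0117) and adipocyte markers (0.0211) in SMRT KO against control, both lower, and stellate cell markers in double KO against control, lower (0.042).

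Of the 89 named gene values, 1, 35 and 36 were calls in the 3 comparisons, and only these could lose a call. With only the 2 groups in the fit 24 of these calls were lost, and 12 to 30 when 1 mouse was left out. At most 1 was lost under each scaling, array weights or the mean of probe sets. The share of higher genes in double KO against control was 62.0% as deposited and 57.1% to 61.4% under the 3 other scalings. List directions turned under a scaling where the median was near 0 and the list did not pass camera: the corepressor, bile acid, acute phase and pancreatic lists in double KO against control, and the LXR, stellate and pancreatic lists in SMRT KO against control.

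The titles number the mice 1 to 3 in each group, and nothing in the labels says that a number marks a pair. Same-numbered mice deviated together with correlations of -0.08 to 0.12 across genes, not above 0.1 in every pair, and 4 of 9 sets of the same number matched best with their own number. With the replicate number as a block, 2, 152 and 195 genes were called in the 3 comparisons, 29 lists passed, and 13 named calls were lost and 1 gained, Nlrp1c-ps in SMRT KO against control (adjusted p = 0.0305). Array signals near background limit what can be seen of weakly expressed genes, and 3 mice per group limit the rest.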

Other observations

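All tests in this part were chosen after the results were seen, except the counts over other splits of the mice.

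Gene families defined by the letters of their symbols, 642 with at least 5 members, were tested with camera. In double KO against control livers the sulfotransferases (Sult, 21 genes, 6 called higher, median log2 fold change 0.09, adjusted p = 0.00148), the acyl-CoA thioesterases (Acot, 12 genes, 3 higher, median 0.33, 1.96e-05), the mu-class glutathione transferases (Gstm, 6 genes, 1 higher, median 0.47, 2.28e-05) and the Abcg transporters (6 genes, 1 higher, median 0.21, 0.00769) were higher. Besides Sult1e1, Sult2a1, Sult2a3 and Sult2a7, the called sulfotransferases were Sult2a4 (log2 fold change 1.17) and Sult2a5 (1.94). The Sult2a genes are close copies of each other, and whether their probe sets tell them apart is not analysed here. In double KO against SMRT KO livers the guanylate-binding proteins, which respond to interferon, were lower (Gbp, 10 genes, 1 called lower, median -0.27, adjusted p = 0.01). In SMRT KO livers the ribosomal proteins of the large subunit had a median of 0.12 (Rpl, 45 genes, 0 called by limma, adjusted p = 4.34e-05). The prolactin family (Prl, 21 genes, 0 called) was lower in SMRT KO (median -0.21, adjusted p = 1.03e-05) and double KO livers (-0.125, 0.00735), and the taste receptors (Tas, 38 genes, 0 called) in SMRT KO livers (-0.0865, 0.00341). For each of these families the adjusted p was 0.998 with an estimated correlation, and their directions were the same under the 3 other scalings.

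Some genes near Ncor1 differed between SMRT KO mice and the mean of the other groups. Among the 400 tested genes nearest Ncor1, 8 had p under 0.001 for SMRT KO against the mean of the other groups. Of 279 windows of 400 neighbouring genes elsewhere, 1.08% reached that count (median 2). The windows overlap their neighbours, so they are not independent and shares of them are coarse. Among the genes nearest Ncor1, SMRT KO against control had 4 (reached by 3.94%), double KO against SMRT KO 9 (17.56%) and double KO against control 2 (94.27%). In Lyrm7, Ulk2, Nlrp1c-ps and Xaf1, the 4 of them with p under 0.001 in SMRT KO against control, double KO livers showed 10.6% of the SMRT KO shift, from -6.2% in Lyrm7 to 47.5% in Ulk2. These genes were chosen for the pattern, and Nlrp1c-ps was near background in control (3.88) and double KO livers (4.08), so the low share excludes nothing, and loss of SMRT, which both knockouts share, cannot be told apart from the other explanations. A haplotype linked to the floxed Ncor1 allele, which control and double KO mice carry, is a candidate explanation: 4 of the 30 genes called for SMRT KO against the mean of the other groups lay there, against at most 3 in another window, but at p under 0.001 the highest other window also held 8, so it cannot be told apart from chance, and the labels do not give the Ncor1 allele of the SMRT KO mice.

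Olfactory and vomeronasal receptor genes, which the liver is not known to use, had slightly lower values in both knockouts, as did the prolactin and taste receptor families above in SMRT KO. Over the 1394 olfactory and vomeronasal genes the median log2 fold change was -0.12 in SMRT KO, where 76.2% were lower, and -0.10 in double KO, where 72.7% were, and it kept its sign under the 3 other scalings, with the smallest size after quantile normalization (-0.0604 and -0.0608). A shift of all dim probe sets alike is argued against by dim genes of other families matched on level, whose median was -0.0123 in SMRT KO, but a shift of genes the liver does not use, whatever their family, stays open. Control replicate 1 had a receptor median of 4.13, against 3.73 to 3.91 in the other 8 livers, and without it the median was -0.0646 in SMRT KO and -0.0388 in double KO. That array may carry part of the pattern, and its share cannot be told apart from a difference between the groups, since the remainder was over 0.5 of the shift in the SMRT KO and under it in the double KO.

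The thyroid hormone-induced genes were lowest in SMRT KO replicate 3. Whether their lower level in SMRT KO livers rests on this 1 mouse cannot be decided here. Their mean, relative to the control mean, was -0.113, -0.00138 and -0.358 in SMRT KO replicates 1, 2 and 3. In control replicates 1, 2 and 3 it was 7.106e-05, -0.0501 and 0.05005. Without SMRT KO replicate 3 the median of the list was -0.0493 against -0.15 with it, and the call was lost. That mouse was left out after its values were seen to be the lowest, so a smaller median could be foreseen. The fit also had fewer mice. Genes outside the list with the same levels had a median of -0.0138 over 1000 draws, which argues against a general shift of expressed genes of that size. Of the draws 0% were as low as the list. The list had already passed camera against other genes, and drawn genes need not vary together, so this share adds no support. Whether SMRT KO replicate 3 differed in biology or in handling was not tested.

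Other splits of the 6 mice of a comparison into 3 and 3 number 10, the real split included, too few for a share under 0.05. For SMRT KO against control 2 splits gave at least the 1 called gene, with 1 as the highest of the others. For double KO against control 1 split, the real one, gave 187 genes and the highest other gave 0. For double KO against SMRT KO 1 split, the real one, gave 263 genes and the highest other gave 0.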
